A study of Mus musculus with 2 samples.

How the data were processed

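The samples were immune cells of the ileal lamina propria, the connective tissue under the gut epithelium, from germ-free mice colonized with a single bacterium. The mice received either wild-type Bifidobacterium breve or a Δchat strain that per the labels makes no acetylcholine, with 4 mice per group. The design text gives 4 weeks of colonization and the treatment protocol gives 5 weeks, and nothing in the labels settles which is right. Live CD45+ cells were enriched on a Percoll gradient and sorted, so the data cover immune cells that passed this gate. Each group was profiled as 1 droplet-based single-cell library, and library preparation and bacterial strain therefore cannot be told apart. The deleted gene belongs to the bacterium, so mouse transcript counts could not be used to check the labels.

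The values deposited were raw counts of unique molecular identifiers (UMIs) per gene and barcode, per the file headers, after barcode filtering. Reads were processed with Cell Ranger 7.2.0 against the mouse build GRCm38, per the submitters' processing notes. Whether counting used the strand or included introns is not given in the sources used here. Besides genes, the files held counts of 4 antibody tags per library, named M1 to M4, which the labels do not describe. The number of tags equals the number of mice per group, but no label says that a tag marks a mouse. Barcodes were assigned to a tag by an Otsu threshold on the log10 tag count of each tag and library, and barcodes with no tag or with more than 1 tag were left out.

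Cells were kept with at least 300 genes, at least 500 UMIs and under 10% mitochondrial UMIs. Scrublet scores (scanpy 1.11.5, scikit-image 0.26.0) with the tool's own threshold called 88 barcodes in the WT library and 1 in the Δchat library. That caller had therefore not worked, and the score threshold was set instead, after seeing the data, so that the share of single-tag barcodes above it met the within-tag doublets expected from barcodes with more than 1 tag. The score parted multi-tag from single-tag barcodes only weakly, with an area under the curve of 0.630 and 0.634, so doublets may remain within tags. Both libraries were clustered together on 2000 variable genes, 30 principal components and 15 neighbours, with Leiden resolution 1.5 (igraph 0.11.9). Immunoglobulin, T cell receptor, mitochondrial, ribosomal and sex-linked genes were left out of the clustering genes. The pool of T, NK and innate lymphoid cells was clustered again at resolution 2, and the pool of myeloid and other cells at 1.5. Clusters were named from markers of 28 classes, with a mean score of at least 1, a margin of 0.25 over the next class and at least 3 markers found in 10% of cells. The naming threshold was set after seeing the data, and 10 of 49 clusters stayed unnamed. Names are written as X-like because they rest on markers alone.

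Per library and class, counts were summed and scaled to a common total (CPM), an own computation. Shares carry exact (Clopper-Pearson) 95% binomial intervals, and ratios of summed counts carry exact conditional intervals at the same level. Intervals cover counting error only, not variation between mice or library preparations. A count of 0 is given with the value that 3 counts would make, which is not an exact 95% limit. Isotypes with a count of 0 carry the exact limit instead. The 3 tables of samples, tests and alternatives, the gene lists, the markers and the rule for named genes were fixed before the data were examined. They assumed 1 sample per group and no test between groups, and the library-level values follow them.

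Tests across tags were added after seeing that the files hold them. Counts were summed per tag and class for classes with at least 10 cells in at least 7 of the 8 tagged subsamples. They were compared with edgeR 4.0.16 (quasi-likelihood test, TMM factors, low-count filter, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested in a class and a threshold of 0.05. All adjusted p-values of single genes come from this test unless DESeq2 1.42.0 is named. Single values were compared by exact two-sided permutation tests of 4 against 4 tags, whose smallest p is 0.0286. The p-values measure only the spread between tagged subsamples, which may be technical, and free RNA is shared by all tags of a library. Gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over 67 list and class pairs, and again with an estimated correlation.

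On simulated counts drawn from these subsamples, a 2-fold change was recovered for 90% of changed genes in B-like cells over 10062 genes and for 59% in plasma-like cells over 8639 genes. The recovered share was 52% in CD4 T-like, 67% in germinal centre B-like, 60% in CD8 T-like, 59% in ILC3-like and 56% in NK and ILC1-like cells. For a 1.5-fold change it was 54% in B-like cells and between 10% and 21% in the other classes. With no change simulated, 5 genes were called in B-like cells and 0 in the other classes. With changes simulated, unchanged genes made up 7.1% of calls in B-like, 8.4% in plasma-like and 8.8% in CD4 T-like cells. The share was 9.9% in germinal centre B-like, 8.3% in NK and ILC1-like, 3.9% in CD8 T-like and 3.8% in ILC3-like cells. False calls thus exceeded the adjusted threshold in all classes but CD8 T-like and ILC3-like cells. The list medians, tested on simulated data, recovered 20 of 20 lists shifted by 0.5 on the log2 scale and 0 of 20 unshifted lists.

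Named genes followed a fixed rule. In each class with at least 200 cells in each library, genes with at least 50 UMIs and at least 50 CPM in the higher library were ranked by the bound of the counting interval of the ratio nearest to 1. Up to 10 genes per direction were taken in the largest classes and up to 4 elsewhere. Variable, diversity and joining segments of receptors, mitochondrial and ribosomal genes and unnamed gene models were left out of this ranking. In addition, up to 4 leading members of each gene list per class, all constant-region genes, the genes of the tests of positive cells, the acetylcholine genes with at least 20 UMIs and the class markers could be named. Outside this rule, and chosen after their values were seen, are Hsp90ab1, Hspa8, Dnaja1, H2-Aa, Cd74, Gapdh, Aldoa, Bach2 and Rtp4 in B-like cells, Cmss1 in ILC3-like and NK and ILC1-like cells, the genes that mark clusters, and those for which the text says so. For each of 30 gene lists, the median log2 ratio over members with at least 20 UMIs was placed among 10000 random lists of the same size matched on expression in 20 bins.

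To compare shares of cells with a UMI of a gene, each cell was thinned to 1000 UMIs and shallower cells were left out. A plasma-like cell was assigned an isotype when at least 50% of at least 10 heavy-chain constant UMIs came from 1 isotype. Gene positions and spans came from the GENCODE annotation of GRCm38. Alternatives covered cell filters, doublets, clustering, scaling, filters on low counts, DESeq2, thinning depth and leaving out each tagged subsample in turn. Barcodes with more than 1 tag numbered 931 in the WT and 671 in the Δchat library, untagged barcodes 56 and 58, barcodes failing the filter 679 and 654, and barcodes above the doublet threshold 536 and 404, of which 367 and 286 held a single tag. Other tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0, umap-learn 0.5.12 and matplotlib 3.10.9.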

Results

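Transcripts were counted in single live CD45+ cells sorted from the lamina propria of the ileum of gnotobiotic mice. Each mouse carried a single gut bacterium, Bifidobacterium breve, either the wild-type strain (WT) or a Δchat strain described as unable to make acetylcholine. The 4 mice of each group were profiled as 1 library, so strain and library preparation cannot be told apart, and no label ties a tag to a mouse. The WT library held 9484 barcodes and 43700732 UMIs with a median of 2715.5 UMIs per barcode, and the Δchat library held 7923 barcodes and 40362852 UMIs with a median of 3244. After filtering, 7576 WT cells with 35430559 UMIs and 6331 Δchat cells with 33479960 UMIs were kept, with median depths of 2733 and 3317 UMIs. The 4 antibody tags in each library split the kept cells into subsamples M1 to M4, of 2178, 1444, 3198 and 756 WT cells and 1773, 257, 2317 and 1984 Δchat cells. These held between 1623902 and 14323720 UMIs each. Immunoglobulin genes made up 22.2% of kept UMIs in the WT library and 19.4% in the Δchat library.

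The first question was which immune cells the sorted tissue contained and whether their shares differed between the strains. B-like cells, which bear surface immunoglobulin, made up 52.3% of kept WT cells and 60.2% of kept Δchat cells, a ratio of 1.15 (1.1 to 1.2). Plasma-like cells, the antibody-secreting stage, made up 14.1% (1068 cells) and 9.87% (625 cells), a ratio of 0.700 (0.633 to 0.774). CD4 T-like cells made up 6.77% and 6.10%, a ratio of 0.90 (0.787 to 1.03). Germinal centre B-like cells made up 5.16% and 5.65%, a ratio of 1.1 (0.947 to 1.27), or 0.946 without subsample Δchat M3. ILC3-like cells, innate lymphocytes of mucosal tissue, made up 2.93% and 2.42%, a ratio of 0.825, or 0.527 without Δchat M3, 1.05 without WT M2 and 1.04 without Δchat M1. CD8 T-like cells made up 3.15% and 3.55%, a ratio of 1.13, or 0.974 without Δchat M1. cDC2-like cells, dendritic cells that present antigen to CD4 T cells, made up 1.64% (124 cells) and 0.758% (48 cells), a ratio of 0.463 (0.325 to 0.651).

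Across tagged subsamples the B-like share was 46.1% ± 15.2 in WT and 56.1% ± 14.5 in Δchat (SD, n = 4 each; exact permutation, two-sided p = 0.4). The plasma-like share was 18.2% ± 10.9 against 10.8% ± 5.15 (SD, n = 4 each; exact permutation, two-sided p = 0.257). Only cDC2-like and migratory DC-like cells had no overlap between groups among the 16 classes, and by chance 2.86% of classes would have none. The cDC2-like share was 1.90% ± 0.672 in WT and 0.736% ± 0.321 in Δchat, lower in all 4 Δchat subsamples (SD, n = 4 each; exact permutation, two-sided p = 0.0286, 0.229 adjusted over 16 classes). For migratory DC-like cells, which carry antigen out of the tissue, the shares were 0.478% ± 0.0393 and 0.208% ± 0.125, from 35 and 10 cells (SD, n = 4 each; exact permutation, two-sided p = 0.0286, adjusted 0.229). With a second random seed for the clustering, the ratio of migratory DC-like shares turned to 1.5. No class share passed the adjusted threshold, but a p of 0.0286, the smallest that 4 against 4 can give, does not pass for a single class among 16, so this says nothing on whether shares were stable. Median depth in cDC2-like cells was 9456.5 UMIs in WT and 10602.5 in Δchat, and in B-like cells 2255 and 2891. Unnamed clusters held 6.44% of WT and 5.73% of Δchat cells. All shares are of sorted CD45+ cells and give no cell numbers in the tissue.

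**Figure D1:**
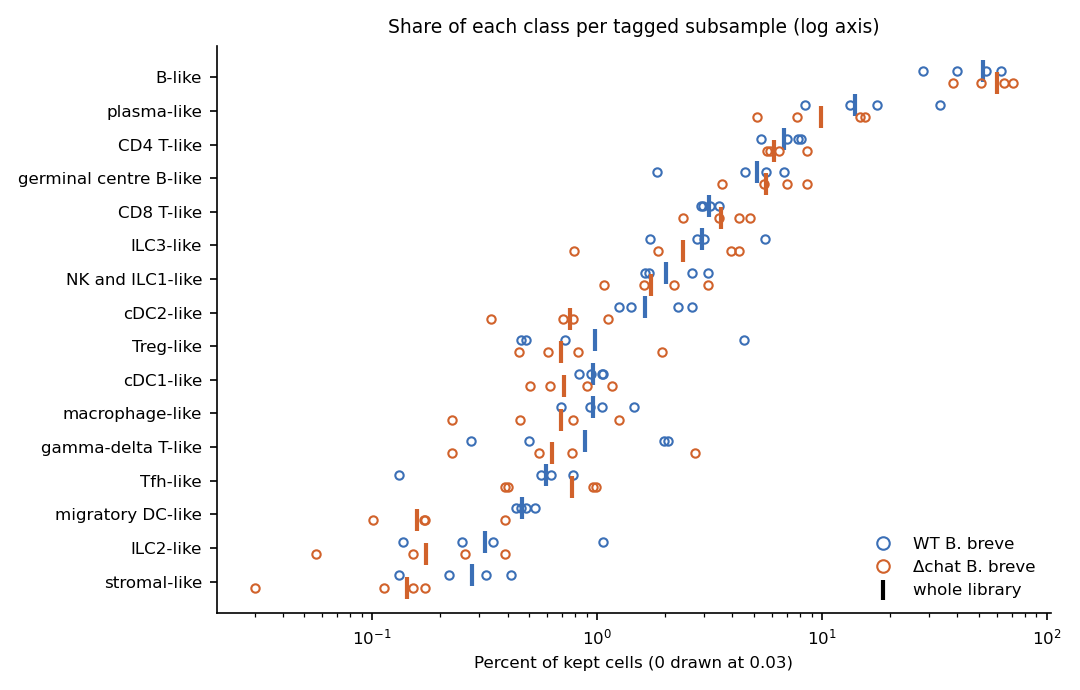
Percent of kept cells in each of 16 cell classes on a log axis, with WT in blue and Δchat in orange. Open circles are the 4 tagged subsamples of each library, vertical bars are the whole library, and shares of 0 are drawn at the left edge.

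Plasma-like cells were examined next, because mucosal antibody is mostly IgA and its secretion depends on the joining chain. Of the cells with a called isotype, 1045 of 1065 WT cells (98.1%, 97.1 to 98.8) and 606 of 616 Δchat cells (98.4%, 97.0 to 99.2) were IgA. IgG1 accounted for 17 WT cells (1.6%) and 10 Δchat cells (1.62%), and IgM, IgG2c and IgG3 for 1 WT cell each and 0 of 616 Δchat cells, which allows up to 0.597% of each. Transcripts were given as CPM, the counts scaled to the class total of a library. Transcripts of Igha, the IgA heavy-chain constant region (GRCm38 chromosome 12, 113254830 to 113260236, minus strand), amounted to 144701 CPM in WT and 91092 CPM in Δchat plasma-like cells. That is a ratio of 0.630 (0.628 to 0.631). Igkc, the kappa light-chain constant region (chromosome 6, 70726435 to 70726966, plus strand), had 58629 CPM and 41119 CPM, a ratio of 0.701. Jchain, which joins IgA monomers (chromosome 5, 88519809 to 88527891, minus strand), had 56506 CPM and 57560 CPM, a ratio of 1.02, though as a mean of per-cell CPM the Jchain log2 ratio in plasma-like cells was −0.00959. The lambda gene Iglc2 had a ratio of 1.03.

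The subsample means for Igha in plasma-like cells were 144723 ± 5300 CPM in WT and 90579 ± 2883 CPM in Δchat, with no overlap (SD, n = 4 each; exact permutation, two-sided p = 0.0286). In edgeR, with its scaling factors, the Igha difference was −0.54 log2 (SE 0.14, adjusted p = 0.169) and did not pass. Igkc stood at −0.39 log2 (SE 0.15, adjusted p = 0.295) with no overlap, and Jchain at 0.19 log2 (SE 0.14, adjusted p = 0.645). Of 6 heavy-chain constant genes tested in plasma-like cells, 0 passed over all genes, and Igha, Ighm and Ighg3 were lower when adjusted over the list alone. Ighm had 3566 UMIs in WT and 795 in Δchat, a ratio of 0.283. The only cell called IgM lay in WT M3, and its part of these UMIs was not measured. Ighg3 had 2770 and 39 UMIs and Ighg2c 1959 and 74, but in WT these came chiefly from subsample M3, with 772 and 552 CPM there. Of 8639 genes tested in plasma-like cells, 2 passed, 1 higher and 1 lower, against 1114 at unadjusted p under 0.05 and 95 with DESeq2. The low count depends on the immunoglobulin genes, since with these left out of the fit 150 genes passed, 85 higher and 65 lower. The count fell to 0 without WT M1, without WT M4 or without Δchat M4, and to 1 without WT M3. Simulated 2-fold changes were recovered for 59% of genes in this class. Grik3, a glutamate receptor gene, had 176 ± 7.36 CPM in WT and 309 ± 8.68 CPM in Δchat (SD, n = 4 each; 0.94 log2, SE 0.13, adjusted p = 0.0518), and Aldoa, an enzyme of glycolysis, had the same adjusted p (0.54 log2, SE 0.07). The glycolysis and hypoxia list had a median of 0.26 log2 in these cells (camera, adjusted p = 0.010, and p = 0.0329 with an estimated correlation, 0.245 after adjustment), and its library median fell from 0.15 to 0.05 log2 without Δchat M3.

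**Figure D2:**
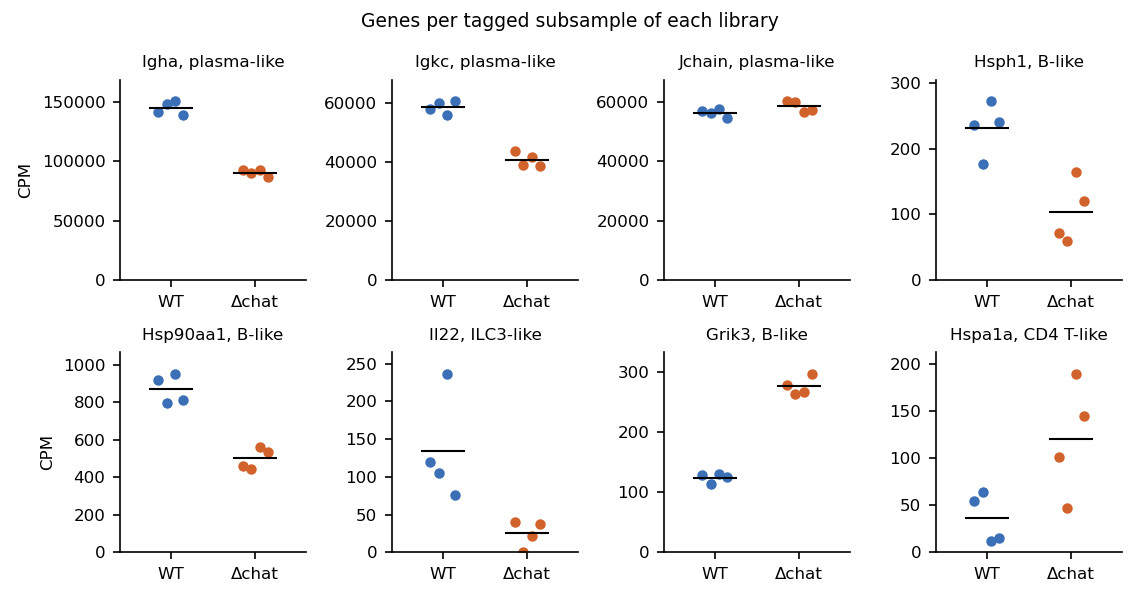
CPM of named genes in each tagged subsample, with WT in blue and Δchat in orange and a line at the mean of each group of 4. Panels show Igha, Igkc and Jchain in plasma-like cells, Hsph1, Hsp90aa1 and Grik3 in B-like cells, Il22 in ILC3-like cells and Hspa1a in CD4 T-like cells.

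B-like cells, with between 300451 and 4876560 UMIs per subsample, allowed the most sensitive test of single genes. The genes of heat-shock chaperones, which fold proteins under stress, stood out among those that fell in Δchat. Hsp90aa1 (chromosome 12, 110690605 to 110702728) fell from 869 ± 77.7 to 500.3 ± 55.4 CPM (−0.75 log2, SE 0.08, adjusted p = 1.4e-06). Hsph1 (chromosome 5, 149614287 to 149636376) fell from 231 ± 40.0 to 104 ± 48.0 CPM (−0.99 log2, SE 0.19, adjusted p = 0.00244). Stip1, a co-chaperone of HSP90 on chromosome 19, fell from 174 ± 25.3 to 85.9 ± 27.1 CPM (−0.99 log2, SE 0.16, adjusted p = 7.2e-04). Hspe1, a mitochondrial chaperone whose gene overlaps Hspd1 on chromosome 1, fell from 741 ± 88.0 to 386 ± 116 CPM (−0.87 log2, SE 0.14, adjusted p = 6.2e-04). Chordc1 fell from 163 ± 25.4 to 84.2 ± 16.8 CPM (−0.87 log2, SE 0.13, adjusted p = 1.8e-04). All values are SD with n = 4 each, and in each of these 5 genes all 4 Δchat subsamples lay below all 4 WT subsamples.

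Of 12 heat-shock genes tested in B-like cells, 7 fell, 0 rose and 5 did not pass, and the same 7 passed when adjusted over the list alone. The list median was −0.41 log2 (camera, adjusted p = 2.96e-09, and p = 0.0271 with an estimated correlation). None of the 18 list and class pairs that passed camera did so after adjustment with an estimated correlation. Hsp90ab1 (−0.47 log2, adjusted p = 0.0025) and Hspa8 (−0.35 log2, adjusted p = 0.00173) were among the 7, and Hspd1 (−0.78 log2) and Dnaja1 (−0.62 log2) were too but did not pass without WT M3, with adjusted p of 0.0579 and 0.0884. Dnaja1 also did not pass without WT M1 or without Δchat M1. In plasma-like cells the list median was −0.50 log2 (adjusted p = 0.0101, and p = 0.297 with an estimated correlation), with 0 genes called over all genes and Hspe1 when adjusted over the list alone. In germinal centre B-like cells it was −0.25 log2 but the mean −0.07 (SD 0.66; adjusted p = 0.0103, and p = 0.209 with an estimated correlation), with 0 genes called over all genes, and 5 lower and 1 higher, Hspa1a (1.43 log2, SE 0.55), adjusted over the list alone. In CD4 T-like, CD8 T-like, ILC3-like and NK and ILC1-like cells the list did not pass. The medians were −0.17, −0.15, −0.22 and −0.08 log2 but the means 0.16, −0.03, 0.08 and 0.22. Over all genes, Hspa1a and Hspa1b rose in CD4 T-like cells and Hspa1b in NK and ILC1-like cells (adjusted p = 0.0308). Adjusted over the list alone, 3 rose and 1 fell in CD4 T-like cells, and 1 rose and 1 fell in CD8 T-like cells. In ILC3-like cells 3 rose and 2 fell, and in NK and ILC1-like cells 3 rose and 1 fell. Differences between classes were not tested. Without Δchat M3 the library median in germinal centre B-like cells moved from −0.29 to −0.47 log2.

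Genes that rose in Δchat B-like cells were led by Cmss1, Grik3, Tmtc2, Il31ra and Rbm3. Of these, Cmss1, Grik3 and Tmtc2 also rose past the threshold in CD4 T-like cells, so their rise was not particular to B-like cells. Grik3 (chromosome 4, 125490700 to 125714173) rose from 124 ± 7.2 to 276 ± 15.1 CPM (SD, n = 4 each; 1.19 log2, SE 0.08, adjusted p = 3.4e-09). Tmtc2, which codes for a membrane protein of the endoplasmic reticulum, rose from 113 ± 20.1 to 211 ± 16.5 CPM (1.03 log2, SE 0.10, adjusted p = 4.2e-07). Il31ra, a cytokine receptor gene, rose from 146 ± 16.4 to 250 ± 39.6 CPM (0.91 log2, SE 0.10, adjusted p = 2.5e-06). Cmss1 rose from 10839 ± 414 to 18502 ± 1171 CPM (0.80 log2, SE 0.04, adjusted p = 5.9e-11). Its span on chromosome 16 (57302000 to 57606864, minus strand) contains Filip1l on the opposite strand, which rose by 0.53 log2 (adjusted p = 1.8e-04), and reads could belong to either gene. Rbm3, an RNA-binding protein gene induced by mild cold, rose from 224 ± 26.0 to 367 ± 43.4 CPM (0.73 log2, SE 0.09, adjusted p = 1.9e-05). Gpx4, which repairs oxidized lipids, rose from 72.0 ± 7.46 to 111 ± 2.21 CPM (0.71 log2, SE 0.09, adjusted p = 1.9e-05). None of these genes overlapped between the groups of 4 subsamples.

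Of 10062 genes tested in B-like cells, 651 passed, 360 higher and 291 lower in Δchat, against 2074 at unadjusted p under 0.05 and 360 with DESeq2. With class totals and no scaling factors the split was 272 higher and 411 lower, so the balance of directions depends on scaling. The count was 321 without WT M1, 424 without WT M2, 287 without WT M3 and 416 without Δchat M4. Of the 651 genes, 59 were immunoglobulin genes. Simulated 2-fold changes were recovered for 90% of genes in this class.

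The constant regions of immunoglobulins were compared in B-like cells to learn whether they moved together, and they did not. Igha fell from 625 ± 46.3 to 383 ± 73.3 CPM (SD, n = 4 each; −0.75 log2, SE 0.08, adjusted p = 3.7e-06) and Jchain from 387 ± 23.7 to 221 ± 16.3 CPM (−0.79 log2, SE 0.07, adjusted p = 3.2e-07). Igkc fell by 0.69 log2 (SE 0.06, adjusted p = 1.2e-07) and Ighm, the IgM heavy chain, by 0.39 log2 (SE 0.06, adjusted p = 1.8e-04). Iglc3 rose by 0.39 log2 (SE 0.06, adjusted p = 7.3e-04), and Ighd, the IgD heavy chain, did not pass (−0.12 log2, adjusted p = 0.329). Of the heavy-chain constant genes in B-like cells, 2 fell and 0 rose, with a list median of −0.40 log2 (camera, adjusted p = 3.33e-04, and p = 0.00561 with an estimated correlation, which is 0.0940 after adjustment and does not pass). The library median of this list moved from −0.45 to −0.27 log2 without WT M3. Light-chain constant genes had a median of 0.23 log2 and a mean of 0.04 while the test pointed lower. Counts of Igha, and of Jchain, which is not a constant region, were also met in T-like cells. In CD4 T-like cells Igha stood at −1.12 log2 and Jchain at −0.86 log2, lower than in B-like cells. Free RNA from plasma cells may therefore account for the falls of these genes in B-like cells. The part of their counts that B cells themselves contribute was not measured.

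Antigen presentation and energy metabolism were compared in B-like cells through fixed gene lists. Of 15 genes for MHC class II and costimulation, 6 rose, 0 fell and 9 did not pass, and 8 rose when adjusted over the list alone. H2-Aa rose by 0.19 log2 (SE 0.04, adjusted p = 0.00295), H2-Eb1 by 0.23 log2 (SE 0.04, adjusted p = 0.00119), Cd74, the invariant chain, by 0.18 log2 (SE 0.03, adjusted p = 0.00105) and H2-DMb2 by 0.30 log2 (SE 0.06, adjusted p = 0.0032), all with no overlap between subsamples. The list median was 0.12 log2 (camera, adjusted p = 0.010, and p = 0.111 with an estimated correlation). Short genes in general were higher in Δchat B-like cells, with medians of 0.15 log2 in the shortest bin by gene span and 0.13 in the next. Whether this list rose beyond genes of like span was not tested. Of 19 glycolysis and hypoxia genes, 6 rose, 1 fell and 12 did not pass, with a median of 0.30 log2 (adjusted p = 9.24e-04, and p = 0.0632 with an estimated correlation). Adjusted over the list alone, 8 rose and 1 fell, and the library median moved from 0.28 to 0.16 log2 without WT M1. Gapdh rose by 0.52 log2 (SE 0.08, adjusted p = 4.0e-04) and Aldoa by 0.42 log2 (SE 0.08, adjusted p = 0.0025), both enzymes of glycolysis. P4ha1, a collagen prolyl hydroxylase, fell by 0.71 log2 (SE 0.12, adjusted p = 9.2e-04). Psmb8, a subunit of the immunoproteasome, rose by 0.46 log2 (SE 0.08, adjusted p = 0.0016), and Bach2, which restrains plasma cell fate, fell by 0.21 log2 (SE 0.04, adjusted p = 0.0067).

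Type I interferon response genes in B-like cells had a median of 0.55 log2 (camera, adjusted p = 0.010, and p = 0.417 with an estimated correlation). Over all genes, 2 of them rose, Isg15 by 1.99 log2 (SE 0.51, adjusted p = 0.0222) and Rtp4 by 1.82 log2 (SE 0.46, adjusted p = 0.0205). Both depended on single subsamples. The Isg15 edgeR log2 fold in B-like cells was 1.11 (adjusted p = 0.168) without Δchat M4 and did not pass without WT M2 (1.79) or without WT M3 (1.70). The Rtp4 edgeR log2 fold in B-like cells was 0.92 (adjusted p = 0.145) without Δchat M4 and did not pass without WT M1 (1.97), without WT M2 (1.73) or without WT M3 (1.68). In the whole libraries the median of the list was 0.67 log2, and −0.02 log2 without Δchat M4. No interferon change is therefore given for B-like cells. In CD4 T-like cells 17 of 20 genes of the list were higher in Δchat, with a median of 0.34 log2 (camera, adjusted p = 9.24e-04, and p = 0.102 with an estimated correlation, 0.528 after adjustment) and 0 genes called over all genes or over the list alone. The library median there was 0.34 log2, and 0.18 log2 without WT M3, the lowest of the 8 values without 1 subsample.

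Germinal centre B-like cells, where B cells mutate their receptors, were tested for the same genes. Of 7654 genes, 21 passed, 19 higher and 2 lower, against 882 at unadjusted p under 0.05, 59 with DESeq2 and 56 with immunoglobulin genes left out. The count was 2 without WT M1, without WT M2 or without Δchat M4, 4 without WT M3, 12 without Δchat M1 and 36 without Δchat M2. Only 2 genes passed whichever subsample was left out, both chosen after their values were seen. Gm8797, an unnamed gene model, rose by 1.30 log2 (SE 0.13, adjusted p = 5.7e-04), and Igkv6-32, a kappa variable segment, fell by 3.98 log2 (SE 0.48, adjusted p = 0.0026). Plac8 had 131 ± 90.3 CPM in WT and 16.0 ± 24.1 CPM in Δchat (SD, n = 4 each) and did not pass (−2.69 log2, SE 0.61, adjusted p = 0.0770). Bcl6, the regulator of germinal centre fate, did not pass (−0.12 log2, SE 0.23, adjusted p = 0.920).

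In CD4 T-like cells, with between 63925 and 531900.0 UMIs per subsample, 30 of 5867 genes passed, 21 higher and 9 lower. At unadjusted p under 0.05 there were 434, and DESeq2 called 22. Immunoglobulin genes made up 11 of the 30, and with these left out of the fit 9 genes passed, all higher. The count was 18 without WT M2, 12 without WT M3 and 18 without Δchat M4. Tmtc2 rose from 110 ± 18 to 283 ± 26.0 CPM (SD, n = 4 each; 1.38 log2, SE 0.17, adjusted p = 7.2e-05). Cmss1 rose by 0.93 log2 (SE 0.15, adjusted p = 0.0033) and Grik3 by 1.02 log2 (SE 0.17, adjusted p = 0.0035). The stress-induced chaperone gene Hspa1b (chromosome 17, 34956436 to 34959238) rose from 72.2 ± 34.4 to 214 ± 95.1 CPM (SD, n = 4 each; 1.62 log2, SE 0.28, adjusted p = 0.0067). Without WT M3 its adjusted p was 0.0776. Heat-shock genes went both ways in these cells, with 6 of 13 higher and 7 lower. Hspd1 fell by 0.81 log2 (adjusted p = 0.375 over all genes and 0.0170 over the list alone). Differences from B-like cells were not tested. Reads of Hspa1b and its near-identical neighbour Hspa1a are hard to assign to either gene. The immunoglobulin genes Igha (−1.12 log2, SE 0.16, adjusted p = 6.2e-04) and Igkc (−0.97 log2, SE 0.16, adjusted p = 0.0030), which T cells do not transcribe, fell in all 4 Δchat subsamples.

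Immediate-early genes, which cells switch on within minutes of handling or stimulation, were followed as a list because tissue dissociation raises them too. In CD4 T-like cells 13 of 14 were higher in Δchat, with a median of 0.27 log2 (camera, adjusted p = 3.37e-05, and p = 0.0150 with an estimated correlation, 0.167 after adjustment). Over all genes 1 of them rose, Ier2 by 0.69 log2 (SE 0.15, adjusted p = 0.0396), and it passed in only 2 of 8 fits without 1 subsample. Adjusted over the list alone, Ier2 and Egr1 rose. In ILC3-like cells 9 of 13 were higher, with a median of 0.18 log2 (adjusted p = 0.0103, and p = 0.146 with an estimated correlation). The list did not pass in plasma-like cells, where 12 of 13 were higher (median 0.28 log2, adjusted p = 0.0770), or in B-like cells (median −0.05 log2, adjusted p = 0.273), where 1 gene of it rose and 4 fell.

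Regulators of T helper fate were compared in T helper cells as shares of cells with a UMI at 1000 UMIs per cell. Gata3, the regulator of type 2 cells, was found in 12.4% of 604 WT and 6.91% of 463 Δchat cells of the CD4 T-like, regulatory T-like and follicular helper T-like classes pooled, with 25.2% and 21.1% in unthinned cells (n = 4 each; exact permutation, two-sided p = 0.114). Foxp3, the regulator of regulatory T cells, was found in 4.47% and 3.89%, and Tbx21, the regulator of type 1 cells, in 8.77% and 8.64%. Background in B-like cells was 0 for Gata3 in WT and 0.0272% in Δchat. With 38 shares tested, no single share could pass after adjustment, so these tests cannot tell a change from none. Of the pooled cells, 28 of 632 WT and 16 of 479 Δchat cells were too shallow and left out, and median depths before thinning were 2782.5 and 3600 UMIs. As a list, regulatory T cell genes had a median of −0.33 log2 in CD4 T-like cells (camera, adjusted p = 0.0102, and p = 0.148 with an estimated correlation), with 0 genes called. Its library median moved from −0.33 to −0.14 log2 without Δchat M1 and to −0.66 log2 without Δchat M3.

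CD8 T-like cells, which include the cytotoxic cells of the tissue, had 18 of 3650 genes past the threshold, 10 higher and 8 lower, against 424 at unadjusted p under 0.05 and 22 with DESeq2. With immunoglobulin genes left out 8 passed, all higher. The count was 29 without Δchat M2 and 37 without Δchat M3. Filip1l rose from 291 ± 55.9 to 563 ± 53.0 CPM (SD, n = 4 each; 0.99 log2, SE 0.17, adjusted p = 0.0021), and Igha fell from 443 ± 95.4 to 188 ± 32.6 CPM (−1.16 log2, SE 0.18, adjusted p = 0.0012). All 13 tissue residency genes tested were lower in Δchat CD8 T-like cells, with a median of −0.48 log2 (camera, adjusted p = 1.66e-04, and p = 0.0556 with an estimated correlation). Over all genes 0 of them passed, and adjusted over the list alone 1 did, the gut-homing receptor gene Ccr9 (−0.78 log2, SE 0.24). The library median of −0.53 log2 moved to −0.21 without Δchat M1, −0.36 without WT M4 and −0.99 without Δchat M3. The class pools a cluster marked by Lef1 and Dapl1 with one marked by Itgae and Itga1, which held 4.12% and 0.677% of Δchat M1 cells, so the list may also follow this mix.

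ILC3-like cells were examined for the cytokines that sustain the gut barrier. Il22 (chromosome 10, 118204942 to 118210047, plus strand), which acts on epithelium, fell from 134 ± 70.6 to 25.1 ± 18.5 CPM (SD, n = 4 each; −2.35 log2, SE 0.43, adjusted p = 0.0040). All 4 Δchat subsamples lay below all 4 WT subsamples. The whole libraries held 88 Il22 UMIs in 222 WT cells and 14 in 153 Δchat cells, a CPM ratio of 0.186 (0.0979 to 0.329). Without Δchat M3 the value was −2.09 log2 with adjusted p = 0.174, and the low-count filter kept Il22 in only 5 of 8 such fits. In cells thinned to 1000 UMIs, 24 of 208 WT cells (11.5%, 7.53 to 16.7) and 3 of 147 Δchat cells (2.04%, 0.423 to 5.85) held an Il22 UMI. The subsample shares were 10.9% ± 6.06 and 2.92% ± 3.39 (SD, n = 4 each; exact permutation, two-sided p = 0.0857). Unthinned shares were 15.8% and 7.19%, thinning left out 14 and 6 cells, median depths were 2763.5 and 3412 UMIs, and background in B-like cells was 0. Il17a was found in 0 of 208 and 0 of 147 thinned cells, where 3 cells would make 1.44% and 2.04%.

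In all, 9 of 2987 genes passed in ILC3-like cells, 5 higher and 4 lower, against 213 at unadjusted p under 0.05, 8 with DESeq2, 5 with immunoglobulin genes left out and 16 without Δchat M2. Cmss1 rose by 0.89 log2 (SE 0.13, adjusted p = 3.3e-04), as in B-like cells. Only 3 of 15 MHC class II genes could be tested, with a median of 1.25 log2 (camera, adjusted p = 0.010, and p = 0.0208 with an estimated correlation, which is 0.199 after adjustment and does not pass). Cd74 (1.25 log2, SE 0.31) and H2-Aa (1.64 log2, SE 0.46) passed only when adjusted over the list alone, and 0 over all genes. In the library sums of ILC3-like cells Ighm was also at least 1.5 times higher in Δchat. Transcripts brought by B cells, as free RNA or doublets, were not told apart from those of ILC3-like cells. NK and ILC1-like cells had 12 of 2640 genes past the threshold in 7 subsamples, 5 higher and 7 lower, against 213 at unadjusted p under 0.05 and 8 with DESeq2. The count was 7 without WT M1, 7 without WT M2 and 5 without WT M3. Slc6a20a, an amino acid transporter gene chosen after its values were seen, fell by 2.90 log2 (SE 0.53, adjusted p = 0.0054) and Igha by 1.26 log2 (SE 0.21, adjusted p = 0.0023). Slc6a20a marked a single cluster of this class that held 25 WT and 3 Δchat cells, so its fall goes with fewer of these cells and is not shown within a cell type.

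Mouse genes that make, break down or sense acetylcholine were measured because the bacterial gene removed serves its synthesis. Only 8 of 26 such genes had enough UMIs across all kept cells, and their median was −0.11 log2, at percentile 27.8 of random lists. It was −0.22 without WT M3 and turned to 0.04 without Δchat M4. The receptor subunit Chrnb1 had 8.89 CPM in WT and 7.77 CPM in Δchat, and Chrna9 had 2.12 and 2.87 CPM. Chrnb2, another receptor subunit, had 1.24 and 0.717 CPM, a ratio of 0.577 (0.336 to 0.970; n = 4 each; exact permutation, two-sided p = 0.0571). The degrading enzyme Ache had 1.02 and 0.956 CPM. Transcripts this rare set no limit on the response of the cells to acetylcholine.

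A last comparison asked whether the cell classes differed each in its own way or shared a direction. Of 2062 genes tested in all 7 classes, 429 had the same direction in each class, 205 higher and 224 lower in Δchat, or 20.8% where 1.56% would be met with independent classes. The classes come from the same subsamples and libraries and are not independent, so 1.56% is too low a baseline. Other splits of the 8 subsamples gave between 37 and 258 such genes. Cmss1 was among them, with 0.80 log2 in B-like, 0.93 in CD4 T-like, 0.92 in CD8 T-like, 0.89 in ILC3-like and 0.67 in NK and ILC1-like cells. The genes higher in every class had a median span of 7085 bases and included 29 ribosomal protein genes. The genes lower in every class had a median span of 83456 bases and included 7 mitochondrial genes, where all genes compared had a median span of 29719 bases. The rank correlation of log2 fold with gene span was −0.373 in B-like cells, −0.337 in plasma-like cells, −0.248 in CD4 T-like cells and −0.0817 in ILC3-like cells. It was −0.331 in germinal centre B-like, −0.379 in CD8 T-like and −0.302 in NK and ILC1-like cells. In B-like cells 32 of 92 ribosomal protein genes rose and 5 fell, and 9 of 13 mitochondrial genes fell. Of the 651 genes called in B-like cells, 192 belonged to the shared set. Grik3 and Tmtc2, with long spans, rose in B-like cells all the same.

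**Figure D3:**
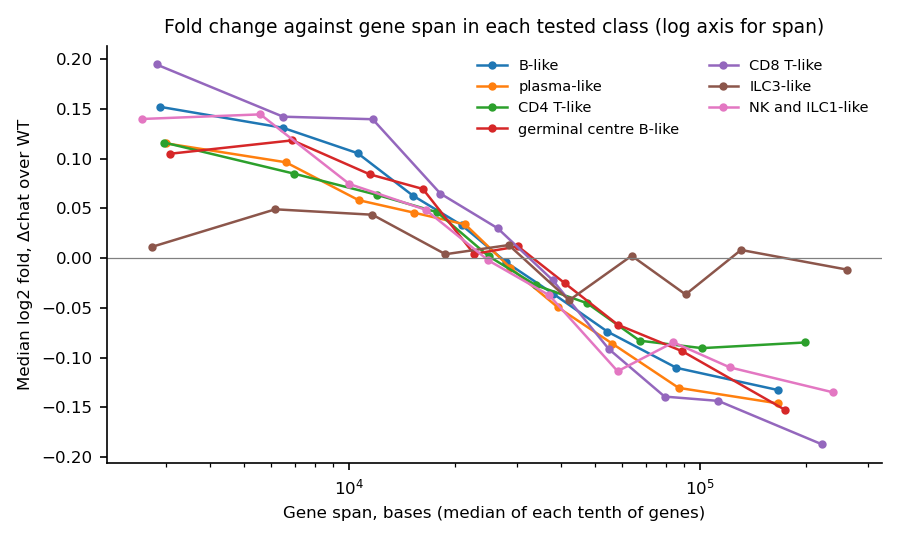
Median log2 fold of Δchat over WT, on the vertical axis, for 10 equal bins of genes ordered by gene span. The horizontal axis gives the median span in bases on a log scale, and each line is 1 of 7 cell classes.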

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

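The comparisons of tagged subsamples in this part were chosen after the tags were seen. In 48 groups of 4 subsamples, the highest or lowest value was compared with the rest by its gap over the range, and 2 stood apart, where chance gives about 1 in 20. Of the clusters, only B-like clusters 1 and 14 were entered, so the rate by chance need not hold for them. Treg-like cells made up 4.50% of subsample WT M4 against 0.459% to 0.719% in the other WT subsamples. B-like cluster 14, marked by the interferon-induced genes Ms4a4c, Ifi27l2a and Oasl1, held 9.78% of Δchat M4 against 0.778% to 1.97% in the other Δchat subsamples. The cause was not tested for either.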

How the results depend on the processing

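The alternatives for gene counts, for camera, and those that leave out a subsample were chosen after the data were seen. All alternatives planned beforehand were run, except that Scrublet with its own threshold, the planned doublet call, was replaced. The cause of these shifts was not tested. Outside the settings that leave out a subsample, 144 of 153 class shares, 41 of 63 gene counts, 1070 of 1254 gene folds (184 weaker, 0 reversed), 947 of 1077 gene ratios, 385 of 428 list medians and all 6 isotype shares stayed the same. Of the 385 list medians, 111 were values with TMM factors that kept their main percentile by construction. Those could not count as moved and say nothing on stability. Scaling by TMM shifted log2 values by 0.11 in plasma-like and CD8 T-like cells, −0.14 in ILC2-like and −0.30 in stromal-like cells.

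The ratio of B-like shares was 1.08 at Leiden 2.5, 1.09 with a second seed and 1.1 with a denominator without plasma-like cells. The CD4 T-like ratio was 0.769 with each library on its own, where migratory DC-like cells had no value and the ILC2-like ratio turned from 0.548 to 2.20, and the CD8 T-like ratio 1.36 with the stricter cell filter. The stromal-like ratio was 0.0798 at Leiden 2.5 against 0.513. The migratory DC-like ratio reversed to 1.5 with a second seed and to 1.5 with immunoglobulin, receptor, mitochondrial, ribosomal and sex-linked genes kept for clustering. Without 1 subsample, the ratios ran from 1.07 (Δchat M1) to 1.34 (WT M3) for B-like, 0.502 (Δchat M3) to 0.831 (Δchat M1) for plasma-like, 0.783 (WT M3) to 0.974 (WT M1) for CD4 T-like and 0.946 (Δchat M3) to 1.25 (Δchat M1) for germinal centre B-like cells.

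Gene counts with no filter on low counts were 1 in plasma-like, 58 in CD4 T-like, 135 in germinal centre B-like, 35 in CD8 T-like, 23 in ILC3-like and 19 in NK and ILC1-like cells. With immunoglobulin genes left out they were 150 in plasma-like, 9 in CD4 T-like, 56 in germinal centre B-like, 8 in CD8 T-like and 5 in ILC3-like cells. DESeq2 gave 360 in B-like, 95 in plasma-like and 59 in germinal centre B-like cells. Median-of-ratios factors gave 4 in plasma-like cells, and class totals with no factors gave 2 in germinal centre B-like cells. The stricter cell filter gave 7 in plasma-like and 70 in CD8 T-like cells, the looser filter 38 in germinal centre B-like cells, and doublets kept 4 in plasma-like cells. Without 1 subsample, counts ran from 287 to 619 in B-like, 0 to 3 in plasma-like, 12 to 36 in CD4 T-like, 2 to 36 in germinal centre B-like, 12 to 37 in CD8 T-like, 7 to 16 in ILC3-like and 5 to 18 in NK and ILC1-like cells. With an estimated correlation 0 lists passed by camera.

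The tag number as a block gave 1 gene in plasma-like and 10 in germinal centre B-like cells. Tag numbers share only a number, and nothing in the labels pairs them. In B-like cells the correlations of same-number subsamples across libraries were 0.0250, −0.0244, 0.0397 and −0.0542, and the highest of all pairs was 0.0745, between WT M1 and Δchat M4.

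The Iglc3 log2 ratio in plasma-like cells was 0.0593 with TMM factors, 0.0604 with median of ratios, 0.0210 with CPM without immunoglobulin genes and 0.0895 as a mean of per-cell CPM, against −0.0545 by class totals, and the Jchain log2 ratio in plasma-like cells was −0.00959 as a mean of per-cell CPM. The ratio of B-like cells with a Cd69 UMI was 1.003 not thinned and 1.04 with 2 UMIs required, against 0.889 thinned. Without 1 subsample, the median of the type I interferon response list in B-like cells ran from −0.0212 (Δchat M4) to 0.925 (Δchat M3) and in cDC2-like cells from −0.476 (WT M3) to 0.338 (WT M1). The interferon gamma response list in CD4 T-like cells ran from −0.0246 (Δchat M3) to 0.297 (Δchat M1), the NF-kB list there from −0.0202 (Δchat M4) to 0.155 (WT M4), also below 0 without WT M1 and Δchat M3, and the ILC3 effectors list in ILC3-like cells from −0.0926 (Δchat M3) to 0.209 (WT M2).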

Other observations

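The tests of gene counts, of lists by camera and of splits of the tagged subsamples were chosen after the results were seen, as were those of a ceiling of UMIs per cell, of free RNA and of a lower constant-region yield for Igha and Igkc, of free RNA for genes with a shared direction, and of a shared shift for Il22. Myeloid cells were too few for tests over all genes, so leading members of the fixed lists are given without adjustment. In macrophage-like cells Acp5, a lysosomal phosphatase of tissue macrophages, had 294 ± 67.9 CPM in WT and 685 ± 120 CPM in Δchat, higher in all 4 Δchat subsamples (SD, n = 4 each; exact permutation, two-sided p = 0.0286). Il15, a cytokine that sustains lymphocytes in tissue, had 132 ± 31.1 and 29.2 ± 23.4 CPM in the same cells, from 47 and 9 UMIs (SD, n = 4 each; exact permutation, two-sided p = 0.0286). In cDC2-like cells Cd74 had 22121 ± 1031 and 27266 ± 2545 CPM and H2-Eb1 7826 ± 535 and 9303 ± 439 CPM, both higher in Δchat with no overlap (SD, n = 4 each; exact permutation, two-sided p = 0.0286 for each). The chemokine gene Ccl17 had 88 UMIs in WT and 2 in Δchat cDC2-like cells, a ratio of 0.0504 (0.00601 to 0.188). These genes were picked for their values. In the 4 myeloid classes 14 of 298 list members (4.70%) showed no overlap between groups, where 2.86% would by chance.

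Type 2 genes in CD4 T-like cells, 7 of 20 measured, had a library median of −0.62 log2, at percentile 0.47 of random lists. It was −0.94 without WT M1 and −1.01 without Δchat M3, but −0.44, at percentile 2.04, without Δchat M1. Il10 had 33 and 12 UMIs and Ccr4 27 and 11. The eosinophil granule gene Ear2 had 106 UMIs in WT and 28 in Δchat over all kept cells, a ratio of 0.280 (0.177 to 0.427). No eosinophil-like class was named, and which cells held Ear2 was not examined, so this shows no change in eosinophils. Of 49 clusters 4 had no overlap between groups, or 8.16% where 2.86% would by chance. Among them, and chosen after its values were seen, B-like cluster 1, marked by Cr2, Bank1 and Cd55, held 2.62% ± 0.843 of all kept WT and 7.50% ± 2.35 of all kept Δchat cells (SD, n = 4 each), or 5.62% and 13.3% of the B-like cells of the libraries. At the WT mix of B-like clusters, a comparison also chosen after the data were seen, all 20 named genes of B-like cells had the same direction. Hsp90aa1 was then at −0.80 log2 against −0.82 and Grik3 at 1.17 against 1.14. Ifi27l2a was at 0.30 against 0.58, the largest move, Cdk8 at 0.41 against 0.59 and Cmss1 at 0.66 against 0.82. Part of some changes thus went with the mix of clusters. The clusters were formed from the same expression values of both libraries and may follow the difference itself. This comparison therefore does not show that cell mix brought that part. In T cells, kappa variable segments chosen after their values were seen went both ways, with Igkv6-23 up by 4.34 log2 (adjusted p = 4.1e-07) and Igkv1-110 down from 193 ± 23.2 to 16.5 ± 3.22 CPM in CD4 T-like cells (SD, n = 4 each).

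The 8 subsamples (7 in NK and ILC1-like cells) were split in all 35 ways to ask whether a chance division can be excluded, which says nothing of library against strain because all tags of a library share its preparation and free RNA. For genes with the same direction in every tested class only the real split gave as many, 429 against 258 in the highest other. The real split also stood alone in the gene count of B-like cells (651 against 38) and germinal centre B-like cells (21 against 1). The same held for ILC3-like cells (9 against 4) and NK and ILC1-like cells (12 against 3). Standing alone among 35 splits is the strongest result this test can give. It was asked of several patterns without adjustment, so it does not exclude chance for any of them. The germinal centre count was 2 without WT M1, without WT M2 or without Δchat M4, 4 without WT M3, 12 without Δchat M1 and 36 without Δchat M2, and the ILC3-like count was 5 with immunoglobulin genes left out and 16 without Δchat M2. Other splits gave at least as many in plasma-like cells (2 against 2, 4 splits), CD8 T-like cells (18 against 18, 2 splits) and for lists by camera (18 against 22, 9 splits). In CD4 T-like cells 2 splits gave at least the real 30, and the other, WT M1, WT M3, Δchat M1 and Δchat M4 against the rest, gave 109. The same split gave 18 in CD8 T-like cells. The first 4 had B-like shares of 53.8% to 70.6% and plasma-like shares of 5.13% to 13.3%, against 28.3% to 51.0% and 14.7% to 33.6% in the rest, and larger shares of a CD4 T-like cluster marked by Lef1. Gene and list results in CD4 T-like cells may therefore follow the cell mix of the subsamples as well as the strain.

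Genes shared a direction in all 7 classes in 429 cases, shorter genes higher and longer genes lower in Δchat. Free RNA from plasma cells is argued against in T-like and innate lymphoid cells, where RNA of the plasma-like profile, at the level Igha shows, brings 50% or more of the CPM difference for at most 0.699% of these genes, while the planned share of immunoglobulin genes decides nothing, as only 6 were tested in every class. RNA capture or RNA quality that differs between the 2 libraries may act through gene span. The correlation with span was negative in all 7 classes, from −0.379 in CD8 T-like to −0.0817 in ILC3-like cells. The weak value in ILC3-like cells leaves this explanation undecided. As each strain had 1 library, preparation and strain cannot be told apart for these genes. A change in the mice that reaches every immune class stays open as a hypothesis.

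The lower Igha and Igkc in plasma-like cells of the Δchat library came without a lower Jchain. A ceiling of UMIs per cell is argued against by Jchain, which lay 0.54 log2 above Igkc at like abundance, and a difference in depth by the Igha ratio of 0.705 in cells of 10000 to 15000 UMIs. Fewer IgA cells are argued against by the share called IgA among cells with an isotype, 98.1% in WT and 98.4% in Δchat. The Igha ratio of 0.628 within cells called IgA adds no support, since nearly all plasma-like cells are among them. Free RNA is argued against by a fall per CD4 T-like cell of 0.184% of that per plasma-like cell. A lower yield of constant-region transcripts in the Δchat library stays open, since Igkc stood at −0.68 log2 in B-like cells too. In the fits of B-like cells 5 of 6 heavy-chain constant genes were lower and 1 higher. Of 4 light-chain constant genes there, 3 were higher, Iglc2 and Iglc3 among them, and 1 lower. A yield lower for all constant-region genes is therefore not what was seen. With 1 library per strain, a lower yield of these transcripts and a lower share in plasma cells of mice with the Δchat strain may each account for it.

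Il22 was lower in ILC3-like cells of the Δchat library. A different mix of clusters is argued against by ratios of 0.121 and 0.240 within the 2 ILC3-like clusters, while depth cannot have lowered it, since the Δchat cells were deeper, so the share of 2.04% at 1000 UMIs per cell adds no support. Il22 lay at percentile 0.2 among 500 genes of like abundance. The pattern was taken up because Il22 was low, so this rank cannot argue against a shift shared by every class. The call rests on 88 and 14 UMIs and ended without Δchat M3, where the value was −2.09 log2. A lower Il22 in mice with the Δchat strain may underlie it, but handling of the 2 libraries stays open. The immediate-early list in these cells had a median of 0.18 log2 and did not pass camera with an estimated correlation (p = 0.146). Of its genes 0 were called over all genes, and 1, Junb, rose by 0.46 log2 when adjusted over the list alone. Of the heat-shock genes there, 3 rose and 2 fell when adjusted over the list alone.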
